A study of Mus musculus with 9 samples.

How the data were processed

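RNA of mouse ovary was measured in 9 libraries, 3 each labelled NC, CTX and HBOT. Per the labels' protocols, total RNA was extracted with TRIzol, polyadenylated RNA was selected with oligo(dT) beads, and libraries were built with the VAHTS mRNA-seq v3 kit and read in pairs on an Illumina instrument. Per the submitters' processing notes, fastp 0.23.4 was used and the genome build was GRCm39 (mm39). The aligner, the counting program and the annotation release are not given in the sources used here. The authors deposited 1 table of FPKM values, with a column per library and 22544 entries, of which 21797 carry Ensembl gene identifiers and 747 are assembled loci with MSTRG names. The columns were matched to the samples through the names in the sample descriptions, and 0 columns stayed unmatched. The column sums ranged from 394046 to 420058, so the deposited FPKM had not been rescaled to a common total.

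Read counts could not be recovered from the FPKM, so the depth of each library is unknown, methods for counts were not used, and the precision of a gene is known only from the spread between libraries. Values were taken as log2(FPKM + 1), without further scaling. Genes with at least 1 FPKM in at least 3 of the 9 libraries were kept, 13338 in total, 262 of them MSTRG loci. One linear model of the 3 groups was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend, 6 residual degrees of freedom). The contrasts were CTX against NC, HBOT against CTX and HBOT against NC. P-values were adjusted by Benjamini and Hochberg over all tested genes of a contrast, and a gene was called at an adjusted p under 0.05. Levels are given as mean and SD of FPKM over the 3 libraries of a group, and fold changes with the standard error of the limma fit.

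The groups, the comparisons, the alternatives, a panel of 15 genes of follicle biology and stress and 34 gene lists of ovarian cell types and pathways were fixed before the data were examined. The lists hold 607 different genes, of which 7 were absent from the table, 72 fell below the filter and 528 were tested. Of the 34 lists 33 had at least 5 measured members and were tested with limma's camera at its preset correlation of 0.01, adjusted over the 33 lists. Each list was tested again with a correlation estimated from the data and with fry. The list means of the libraries were compared in an exact permutation test, whose smallest p for 3 against 3 libraries is 0.1. By a rule set in advance, a comparison in which 0 genes passed names the 5 genes with the smallest p in each direction that have a mean of at least 2 FPKM over the 9 libraries and do not overlap between groups, leaving out predicted genes and pseudogenes without an established name. The rule also names the panel genes and up to 4 members of each list with the smallest p, given here only for called lists. Naming members that go against their list was not part of the rule.

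Opposite changes in CTX against NC and HBOT against CTX were compared with 100 simulated data sets in which the groups do not differ. These were drawn from the residuals of the fit, pooled over the 3 groups, so that the correlation between genes was kept. The spread of an outlying library thus entered all simulated groups. The same was done for the contrasts that share NC.

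The alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, scaling to TPM, by median of ratios and by quantiles, a fit of the 2 groups compared only, replicate number as a block, eBayes without trend or with the robust option, library weights (arrayWeights), a smallest log2 fold change of 1, and each library left out in turn. A correction for GC content and transcript length was added later, with a lowess span of 0.3. It used lengths and sequences of GENCODE M21 on GRCm38, matched by Ensembl identifier for 13058 genes (97.9%), so no coordinates are given. Fits without both HBOT replicate 2 and CTX replicate 1, and without HBOT replicate 2 at a pseudocount of 0.1, were added once these libraries had been seen to stand apart.

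The procedure was tested on simulated data with changes added to 100 genes of each size among 13338. A log2 fold change of 1 was recovered for 51%, 56% and 55% of genes in the 3 contrasts and a log2 fold change of 2 for 90%, 92% and 91%, with 6, 12 and 6 false calls among 13117 unchanged genes. A list shifted by 0.5 was called in each contrast, with 0 other lists. The simulated genes varied independently of each other. The test therefore cannot show how often camera calls an unchanged list whose genes vary together. A covariance of -0.0912 built into the simulated data was estimated at -0.0912, and an added GC trend with a rank correlation of 0.885 was reduced to 0.0022. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.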

Results

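Polyadenylated RNA of mouse ovary was profiled by paired-end sequencing in 9 libraries, 3 in each of 3 groups. The CTX libraries carry the usual abbreviation of cyclophosphamide, an alkylating chemotherapy drug that injures ovarian follicles. The HBOT libraries came, per the design text of the series, from CTX combined with hyperbaric oxygen, and the NC libraries, whose labels name neither treatment, served as the reference. FPKM was given for 22544 genes and assembled loci, and the 13338 that reached 1 FPKM in at least 3 libraries were compared. The FPKM of a library summed to between 394046 and 420058, with 12764 to 13101 genes at 1 FPKM or more and 7.67% to 10.2% of the sum in mitochondrially encoded transcripts. Read depth is unknown, since FPKM keeps no read counts. Fold changes are differences of log2(FPKM + 1), which understate the change of low genes. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these samples.

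HBOT replicate 2 stood apart from the other 8 libraries. In it, 1637 genes lay more than 1 log2 unit from the mean of the other 8 libraries, 552 above and 1085 below, against 173 to 347 genes in each of the others. Its highest rank correlation with any other library, across genes, was 0.907, while each of the others reached at least 0.977. It alone carried genes of the ovulatory response that stayed under 1 FPKM elsewhere, such as the growth factors Ereg (361 FPKM) and Areg (145 FPKM), the prostaglandin synthase Ptgs2 (41.3 FPKM) and the progesterone receptor Pgr (49.1 FPKM). CTX replicate 1 was the farthest library on the second principal component, which held 20.2% of the variance, after 42.4% on the first, where HBOT replicate 2 lay alone.

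**Figure D1:**
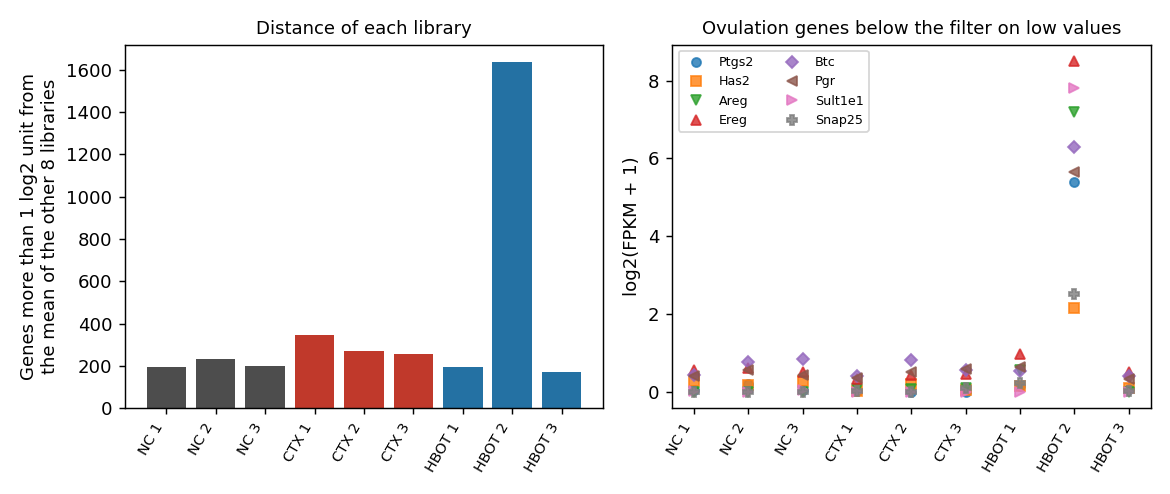
The left panel shows, for each ovary library (NC grey, CTX red, HBOT blue), the number of genes more than 1 log2 unit from the mean of the other 8 libraries, and the right panel shows log2(FPKM + 1) of 8 ovulation genes below the filter on low values, with 1 point per gene and library. HBOT replicate 2 holds 1637 such genes against 347 or fewer elsewhere, and all 8 ovulation genes are highest in it.

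The comparison of CTX with NC asks what cyclophosphamide changed in the ovary. Transcripts of growing oocytes were higher after CTX (adjusted p = 0.221 with an estimated correlation): Gdf9, an oocyte growth factor that drives folliculogenesis, was at 67.8 ± 14.3 FPKM against 38.4 ± 8.74 (mean ± SD, n = 3), and Zp3, which encodes a protein of the egg coat, at 54.1 ± 13.9 against 31.4 ± 7.23. Genes of the corpus luteum were lower (adjusted p = 0.221 with an estimated correlation), among them Akr1c18, the enzyme that breaks down progesterone, at 189 ± 87.9 FPKM against 2367 ± 209. Among single genes, Cdkn2b (ENSMUSG00000073802), an inhibitor of the cell cycle kinases CDK4 and CDK6, was at 3.57 ± 0.922 against 38.9 ± 9.89. Genes of extracellular matrix were lower and genes of blood and immune cells higher. With an estimated correlation 0 of these lists were called (smallest adjusted p = 0.221). Of the 13338 genes tested with limma, 0 passed an adjusted p of 0.05. The smallest adjusted p was 0.169. The fit shares its estimate of spread over all 3 groups, so that of HBOT replicate 2 enters the p-values and standard errors of this comparison.

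The 5 genes with the smallest p among those higher in CTX, none of which passed, included the interferon-inducible GTPase Tgtp1 (ENSMUSG00000078922), at 17.9 ± 5.80 FPKM against 2.73 ± 0.415 (log2 fold change 2.30, SE 0.32, adjusted p = 0.169). Its near-identical copy Tgtp2 makes its reads uncertain. The unannotated locus MSTRG.28856.1, with the smallest p of the 5, was at 21.7 ± 7.39 against 3.71 ± 0.535 FPKM (log2 fold change 2.22, SE 0.28). The class I histocompatibility gene H2-D1 was at 357 ± 75.3 against 133 ± 17.6 FPKM (1.41, SE 0.22), Umodl1 at 10.8 ± 1.64 against 3.85 ± 1.10 (1.30), and Ftdc1 at 12.5 ± 1.49 against 6.76 ± 0.591 (0.80). Among genes lower in CTX, Cdkn2b had a log2 fold change of -3.11 (SE 0.40, adjusted p = 0.169). The stress-response gene Nupr1 was at 38.5 ± 19.6 against 191 ± 14.1 FPKM (-2.40), the growth arrest and DNA damage gene Gadd45a at 32.8 ± 7.42 against 117 ± 15.5 (-1.82). Rgl1, an effector of Ras-related GTPases, was at 8.69 ± 1.85 against 23.2 ± 1.15 (-1.34), and the sphingomyelin synthase Sgms1 at 22.3 ± 0.887 against 38.2 ± 1.31 (-0.75). Of the fixed panel, Cdkn1a, a p53 target that arrests the cell cycle, was at 8.75 ± 1.78 against 18.7 ± 3.25 FPKM (-1.01). Amh, a product of growing follicles, was at 228 ± 166 against 92.5 ± 30.6 (1.08), and Hmox1 at 28.5 ± 3.85 against 36.5 ± 3.25 (-0.35). Adjusted over the panel of 15 genes alone, Gdf9, Zp3 and Cdkn1a each had an adjusted p of 0.0589 by limma. Bax (0.20), Foxo3 (-0.03), Ddx4 (0.13), Mki67 (0.14), Vegfa (-0.04) and Sod2 (-0.19) differed by under 0.2 log2 units, and Fshr (0.56, SE 0.41), Star (-0.94, SE 1.14), Cyp17a1 (1.06, SE 1.22) and Cyp19a1 (1.04, SE 0.91) varied widely between libraries. Amh was at 0.53 without CTX replicate 1 and at 1.56 without CTX replicate 3. Cyp17a1 turned with library weights (-0.10), Sod2 (0.16), Vegfa (0.15) and Mki67 (-0.0098) without CTX replicate 1, and Ddx4 (-0.0033) and Foxo3 (0.04) without NC replicate 3. Over all settings Fshr ran from 0.29 to 0.89, Cyp19a1 from 0.45 to 1.98, Star from -1.52 to -0.12, Bax from 0.03 to 0.21 and Cyp17a1 up to 2.68.

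Unadjusted p-values under 0.05 were found for 1065 genes, 699 higher and 366 lower in CTX, where 666.9 would arise by chance. The excess of higher genes depends on the scaling, as 522 of 1055 were higher with median-of-ratios scaling and 560 of 1090 with quantile scaling. With TPM 622 of 1088 were higher. It also depends on the size of the change, as 63 of 153 were higher at an absolute log2 fold change of at least 1. The 3 CTX libraries did not overlap the 3 NC libraries for 2803 genes (21%, where chance gives 10%). Leaving out 1 library moved the unadjusted count to 627 (without NC replicate 2), 698 (without CTX replicate 1) and 2092 (without HBOT replicate 2). Under limma, 31 genes passed in a fit of these 6 libraries alone, 8 of them higher in CTX. That fit leaves out the spread of the HBOT libraries, and 1843 genes had an unadjusted p under 0.05 in it. With a weight estimated for each library 123 passed, 75 higher. In the fit of all groups 8 passed without HBOT replicate 2, among them Tgtp1, H2-Q4 and Sgms1, 9 without HBOT replicate 3, among them Akr1c18, Cdkn2b, Gadd45a and Rgl1, and 1 (Rpl26) without NC replicate 1. Without both HBOT replicate 2 and CTX replicate 1 the count was 16.

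Of 33 gene lists fixed in advance, camera with a preset correlation called 12 in CTX against NC, 7 higher and 5 lower, and 0 with an estimated correlation. The oocyte list had all 24 of its 24 members higher in CTX (mean log2 fold change 0.68, adjusted p = 8.73e-22 by limma's camera, adjusted p = 0.221 with an estimated correlation). Adjusted over the list alone, 24 members passed, against 0 over all genes. They included Dppa3, a maternal factor of the early embryo, at 18.4 ± 0.749 against 11.8 ± 1.09 FPKM, and Nlrp14, expressed in oocytes, at 45.0 ± 7.82 against 27.9 ± 4.85. The CTX libraries lay above the NC libraries for the list mean, and CTX replicate 3 was the closest to NC (0.34 log2 units above the NC mean, against 0.84 and 0.85). The germ cell list, with markers of primordial follicle oocytes, had 11 of 13 members higher (0.20) and was not called (adjusted p = 0.0735). It would have been called without NC replicate 1 (0.26, adjusted p = 0.00939) or without CTX replicate 3 (0.33, adjusted p = 0.00119), and stood at 0.11 without CTX replicate 1 (adjusted p over all settings 0.00119 to 0.429).

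Of 21 measured extracellular matrix genes, 19 were lower in CTX (mean -0.46, adjusted p = 3.51e-12 by limma's camera, adjusted p = 0.221 with an estimated correlation), and only Col6a1 (0.19) and Col6a2 (0.02) were not. Adjusted over the list alone, 3 passed, against 0 over all genes: Timp1, an inhibitor of matrix metalloproteinases, at 47.6 ± 21 against 151 ± 66.8 FPKM, the growth factor Tgfb1, at 14.7 ± 1.42 against 26.8 ± 3.13, and Loxl2, which crosslinks collagen, at 19.1 ± 3.29 against 32.3 ± 3.09. The immediate early genes, transcription factors and regulators induced within minutes of a stimulus, were lower in 13 of 15 (mean -0.85, adjusted p = 3.25e-06, adjusted p = 0.471 with an estimated correlation), with Klf2 (0.14) and Nr4a2 (0.01) the exceptions. Adjusted over the list alone 1 passed, Jun, at 16.1 ± 2.68 against 36.7 ± 5.34 FPKM. Egr1 was at 10.2 ± 2.52 against 38.9 ± 27.7. For this list NC replicates 1 and 2 lay 0.39 and 0.12 above the NC mean. NC replicate 3 was at -0.50, near the CTX libraries (-0.93 to -0.68). The ovulation list was lower in 7 of 8 (mean -0.38, adjusted p = 0.0476, adjusted p = 0.670 with an estimated correlation), with 0 members passing over the list alone. Its call was lost without NC replicate 2 (adjusted p = 0.0510), NC replicate 3 (0.113) or CTX replicate 1 (0.115), and under no filter, TPM, median-of-ratios and quantile scaling, with adjusted p between 0.00206 and 0.154 over 22 settings. Of 10 ferroptosis and iron genes 9 were lower (mean -0.35, adjusted p = 0.00455, adjusted p = 0.221 with an estimated correlation). The ceruloplasmin gene Cp was at 10.8 ± 0.818 against 19.2 ± 6.34 FPKM, while the ferritin heavy chain Fth1 was higher, at 862 ± 49.2 against 702 ± 14.3. Over the list alone 0 passed, and without CTX replicate 1 the list was at -0.21 (adjusted p = 0.0730, over all settings 0.000759 to 0.0730).

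The corpus luteum list, of steroid-secreting cells formed after ovulation, was lower in 8 of 11 members (mean -0.94, adjusted p = 0.000252, adjusted p = 0.221 with an estimated correlation). Akr1c18 and the transcription factor Onecut2 (0.929 ± 0.426 against 6.97 ± 2.84 FPKM) passed over the list alone, 2 against 0 over all genes. The prostaglandin F receptor Ptgfr was at 38.7 ± 26.3 against 112 ± 8.50. Akr1c18 degrades progesterone and marks the late corpus luteum, and the lactate dehydrogenase Ldhb (0.42), the gonadotropin receptor Lhcgr (0.63) and Hsd17b7 (0.29) were higher, not lower. The library means overlapped between groups. Without CTX replicate 1 the list was at -0.54 (adjusted p = 0.0430), and without HBOT replicate 2 as well the call was lost (adjusted p = 0.117, over all settings 1.97e-06 to 0.117).

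Lists of blood and immune cells were higher in CTX. The filter on low values kept 5 of 12 listed neutrophil genes, 8 of 16 for T and NK cells and 6 of 9 erythroid genes. A gene under 1 FPKM in all NC libraries passed it only through higher CTX or HBOT libraries, which favours a rise against NC. All 6 measured erythroid genes were higher (mean 1.81, adjusted p = 1.72e-06 by limma's camera, adjusted p = 0.221 with an estimated correlation), 5 of them passing over the list alone. Hba-a1 was at 271 ± 93.1 against 55.0 ± 30.3 FPKM and Hbb-bs at 204 ± 81.4 against 43.5 ± 26.7. The globin genes have near-identical copies, so the division of reads among them is uncertain. All 5 neutrophil genes were higher (mean 1.21, adjusted p = 0.000206, adjusted p = 0.221 with an estimated correlation), 4 passing over the list alone. They included the cytokine receptor Csf3r (1.5 ± 0.194 against 0.613 ± 0.243 FPKM) and the calgranulin S100a9 (8.44 ± 8.51 against 0.637 ± 0.264). All 21 interferon response genes were higher (mean 0.67, adjusted p = 4.03e-09, adjusted p = 0.471 with an estimated correlation), 2 passing over the list alone, the signal transducer Stat2 (31.9 ± 5.93 against 19.8 ± 1.72 FPKM) and Rtp4 (18.1 ± 4.22 against 8.72 ± 2.85). For T and NK cells 8 of 8 were higher (mean 0.64, adjusted p = 0.000371, adjusted p = 0.221 with an estimated correlation), among them the granzyme Gzma (2.80 ± 2.28 against 0.264 ± 0.189 FPKM). For macrophages 12 of 16 were higher (mean 0.38, adjusted p = 0.000603, adjusted p = 0.556 with an estimated correlation), with the complement component C1qb at 31.5 ± 3.50 against 19.3 ± 1.91 FPKM and Itgam, Cd68, Cd14 and Cx3cr1 not higher. Neither of these 2 lists had a member that passed over the list alone, and without CTX replicate 2 the macrophage list was at 0.26 (adjusted p = 0.0615, over all settings 1.11e-05 to 0.0615). All 22 DNA replication genes were higher (mean 0.29, adjusted p = 0.000746, adjusted p = 0.670 with an estimated correlation), such as the thymidylate synthase Tyms (10 ± 1.0 against 7.54 ± 1.75 FPKM). The library means overlapped and 0 passed over the list alone, and without CTX replicate 1 the list was at 0.13 (adjusted p = 0.212, over all settings 1.67e-06 to 0.212).

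Lists of the remaining cell types and pathways were not called in this comparison. The mean log2 fold change was 0.19 for granulosa cells, -0.04 for theca and steroidogenesis, 0.05 for cholesterol synthesis, 0.19 for cell division, 0.12 for DNA damage repair, 0.11 for apoptosis, -0.07 for antioxidant genes, 0.02 for hypoxia targets, -0.07 for endothelial cells and -0.07 for smooth muscle. The p53 targets had a mean of -0.05 and a median of 0.06, so their mean and median differed in sign. For cholesterol synthesis, hypoxia, complement and surface epithelium, none of them called, the camera direction was opposite to the mean. The cholesterol list would have been called higher without CTX replicate 1 (0.60, adjusted p = 3.49e-07) and lower without CTX replicate 3 (-0.33, adjusted p = 0.00839). For 13 of the 33 lists the CTX and NC libraries did not overlap, where chance gives 10%, each with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. A test with fry called 0 lists in one direction.

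**Figure D2:**
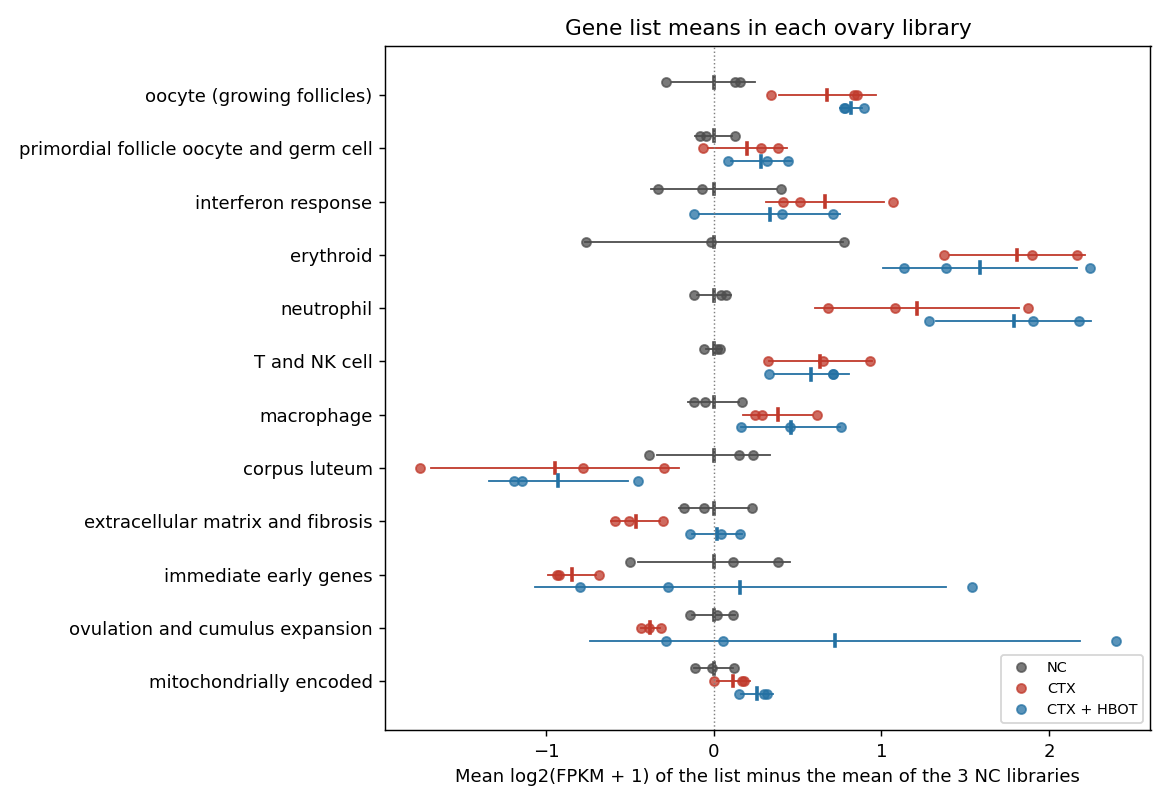
Mean log2(FPKM + 1) of 12 gene lists in each ovary library, as the difference from the mean of the 3 NC libraries (points), with the group mean (tick) and SD (line) for NC in grey, CTX in red and CTX with HBOT in blue. The oocyte list is 0.68 above NC in CTX and 0.82 above it in HBOT, the matrix list is -0.46 in CTX and 0.02 in HBOT, and 1 HBOT library lies far above the others for the immediate early and ovulation lists.

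The comparison of HBOT with CTX asks what hyperbaric oxygen added to the drug. Extracellular matrix genes were higher with HBOT (adjusted p = 0.520 with an estimated correlation), led by Tgfb1 (ENSMUSG00000002603), a growth factor that promotes matrix deposition, at 32.2 ± 4.42 FPKM against 14.7 ± 1.42 (mean ± SD, n = 3), and Timp1 (ENSMUSG00000001131), at 186 ± 25.7 against 47.6 ± 21. Immediate early and ovulation genes were higher too, to a large part in HBOT replicate 2, and with an estimated correlation 0 lists were called (smallest adjusted p = 0.520). The oocyte genes differed little, Gdf9 standing at 76.8 ± 7.49 against 67.8 ± 14.3 FPKM. Interferon genes were lower (-0.33, adjusted p = 0.883 with an estimated correlation), but not called without CTX replicate 2 (-0.14) or without HBOT replicate 2 (-0.10), and 0 of them passed. With limma, 0 of 13338 genes passed an adjusted p of 0.05, and the smallest was 0.180.

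The 5 genes with the smallest p among those higher in HBOT, none of which passed, were Tgfb1 (log2 fold change 1.08, SE 0.14, adjusted p = 0.219), Timp1 (2.03, SE 0.36, adjusted p = 0.579), Sema3d, Asgr1 and Ramp1. The guidance molecule Sema3d was higher (8.43 ± 3.06 against 1.69 ± 0.692 FPKM, 1.78), as were the asialoglycoprotein receptor subunit Asgr1 (3.87 ± 1.34 against 0.820 ± 0.341 FPKM, 1.40) and Ramp1, a partner of the calcitonin receptor-like receptor (5.74 ± 3.13 against 0.871 ± 0.142 FPKM, 1.74). Among those lower in HBOT, the unannotated locus MSTRG.28856.1 was at 3.17 ± 0.951 against 21.7 ± 7.39 FPKM (log2 fold change -2.41, SE 0.28, adjusted p = 0.180). It was followed by the imprinted gene Mest (4.93 ± 0.710 against 10.4 ± 1.60 FPKM, -0.94), Adam33 (-0.80), the glycogen phosphatase subunit Ppp1r3b (-0.83) and Tmem97 (28.0 ± 2.08 against 38.4 ± 1.58 FPKM, -0.44). Of the panel, Cdkn1a was at 23.8 ± 11.5 against 8.75 ± 1.78 FPKM (1.25, adjusted p = 0.0568 over the panel alone by limma), and Cyp17a1, an androgen-synthesizing enzyme of theca cells, at 555 ± 236 against 275 ± 251 (2.02, SE 1.22). Star was at 770 ± 971 against 319 ± 233 (0.51, SE 1.14), Cyp19a1 at 25.3 ± 26.4 against 16.2 ± 12.6 (0.55, SE 0.91) and Hmox1 at 36.8 ± 8.53 against 28.5 ± 3.85 (0.34). The direction of Star turned without CTX replicate 1 (-0.31), without HBOT replicate 2 (-0.70) and with library weights (-1.30), and over all settings it ran from -1.52 to 1.79. Cyp19a1 turned without CTX replicate 2 (-0.39) and without HBOT replicate 1 (-0.27), with 1.97 as its highest value. Cyp17a1 was at 0.39 without CTX replicate 2 and at 3.02 without CTX replicate 1, and Fshr turned without HBOT replicate 2 (0.16) and with library weights (0.42). The others had log2 fold changes of 0.27 for Zp3, 0.26 for Ddx4, 0.27 for Amh, -0.27 for Fshr, -0.23 for Mki67, -0.09 for Bax, -0.14 for Foxo3, -0.43 for Sod2 and -0.29 for Vegfa. Amh turned without CTX replicate 3 (-0.21) and was at 0.83 without CTX replicate 1, and Foxo3 (0.14) and Bax (0.03) turned without HBOT replicate 2. Over all settings Sod2 ran from -0.85 to -0.24, Vegfa from -0.67 to -0.14, Mki67 from -0.35 to -0.08, Zp3 from 0.05 to 0.42, Ddx4 from 0.17 to 0.38 and Hmox1 from 0.22 to 0.56.

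Unadjusted p-values under 0.05 were found for 812 genes, 322 higher and 490 lower in HBOT, against 666.9 by chance, and 1361 genes (10.2%) did not overlap between the groups, where chance gives 10%. The excess of lower genes turned with median-of-ratios scaling (430 of 841 higher), with quantile scaling (440 of 866), without CTX replicate 2 (241 of 478) and without HBOT replicate 2 (400 of 687). At an absolute log2 fold change of at least 1, 79 of 135 were higher. The unadjusted count moved to 478 without CTX replicate 2, 486 without CTX replicate 3 and 448 in a fit of these 6 libraries alone, in which 0 genes passed. It was 1293 without HBOT replicate 1, 1556 without HBOT replicate 3 and 1527 without both HBOT replicate 2 and CTX replicate 1. With library weights 5 genes passed under limma, of them 4 higher (Tgfb1, Sema3d, Ramp1 and Plekhg4) and MSTRG.28856.1 lower. Leaving out NC replicate 3, CTX replicate 1 or CTX replicate 2 let 1 gene pass in each case (MSTRG.24116.10, Kcnk3 and MSTRG.28856.1), and leaving out both HBOT replicate 2 and CTX replicate 1 let 2 pass (Kcnk3 and Lgr5). With no filter on low values 1 passed, the locus MSTRG.25118.1.

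Camera with a preset correlation called 10 lists in HBOT against CTX, 9 higher and 1 lower, and 0 with an estimated correlation. Of 21 extracellular matrix genes 19 were higher (mean 0.48, adjusted p = 4.13e-12 by limma's camera, adjusted p = 0.520 with an estimated correlation), and only Col6a1 (-0.22) and Sparc (-0.08) were not. Adjusted over the list alone 6 passed, against 0 over all genes, among them Ccn2, a matricellular growth factor, at 55.4 ± 13.8 against 26.2 ± 7.70 FPKM, and Loxl2, at 33.1 ± 5.37 against 19.1 ± 3.29. The HBOT libraries lay above the CTX libraries for this list. Fry's mixed test, which asks whether members change whatever their direction, gave an adjusted p of 0.00295. It passed 1 list in CTX against NC, 1 in HBOT against CTX and 4 in HBOT against NC. In one direction fry called 0 lists in HBOT against CTX. Against NC the matrix list of HBOT was at 0.02, with 11 members higher and 10 lower. This was the one list of the 10 called under each of the 23 other settings of camera's preset correlation, at 0.42 to 0.59. Of these settings, the robust option does not enter camera and could not change the call.

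Immediate early genes were higher in 14 of 15 (mean 1.0, adjusted p = 2.25e-08 by limma's camera, adjusted p = 0.654 with an estimated correlation). Adjusted over the list alone 1 passed, the transcription factor Jun, at 32.0 ± 9.08 against 16.1 ± 2.68 FPKM, while the zinc finger factor Egr2 stood at 6.66 ± 8.62 against 0.625 ± 0.207. The phosphatase Dusp1 was lower (-0.50). HBOT replicate 2 lay 1.54 above the NC mean for this list, HBOT replicates 1 and 3 at -0.27 and -0.80. Without HBOT replicate 2 the mean was 0.31 (adjusted p = 0.00395), and without CTX replicate 1 as well 0.27, no longer called (adjusted p = 0.134, over all settings 3.35e-11 to 0.134). The ovulation list was higher in 7 of 8 (mean 1.10, adjusted p = 0.000899, adjusted p = 0.654 with an estimated correlation), with 0 passing over the list alone. Tnfaip6, which stabilizes the cumulus matrix, stood at 63.8 ± 108 against 0.412 ± 0.0831 FPKM, an SD that HBOT replicate 2 set, and the hyaluronan receptor Cd44 at 8.80 ± 4.36 against 4.24 ± 0.389. Without HBOT replicate 2 the list was at 0.26 (adjusted p = 0.0200), and with library weights, or without CTX replicate 1 as well, it was not called (over all settings 8.33e-06 to 0.145).

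The 24 oocyte genes were higher in 23 (mean 0.14, adjusted p = 0.000899, adjusted p = 0.864 with an estimated correlation) and 0 passed over the list alone. Nlrp5, a maternal-effect gene, was at 27.1 ± 2.59 against 19.2 ± 3.75 FPKM. Without CTX replicate 3 the list was at -0.03 (adjusted p = 0.501), without HBOT replicate 2 at 0.10 (adjusted p = 0.151), without CTX replicate 1 at 0.22 and without CTX replicate 2 at 0.23 (adjusted p over all settings 8.48e-07 to 0.501). The germ cell list was higher in 9 of 13 (mean 0.08, adjusted p = 0.0185, adjusted p = 0.766 with an estimated correlation), with Uchl1 at 92.4 ± 4.19 against 72.3 ± 14.9 FPKM and Kit lower (-0.57). Over its list alone 0 passed. It stood at -0.05 without CTX replicate 3 (adjusted p = 0.352), 0.0024 without HBOT replicate 1 (adjusted p = 0.0772), 0.17 without CTX replicate 1 and 0.18 without HBOT replicate 2 (adjusted p over all settings 0.00209 to 0.352). Of 13 mitochondrially encoded genes 12 were higher (mean 0.14, adjusted p = 0.000899, adjusted p = 0.670 with an estimated correlation), with 0 passing over the list alone. The cytochrome b gene mt-Cytb was at 4481 ± 325 against 3785 ± 451 FPKM. The list was at 0.08 without CTX replicate 2 (adjusted p = 0.0275) and at 0.11 without HBOT replicate 2 (adjusted p = 0.0653, over all settings 2.07e-06 to 0.188). The calls of these 3 lists also ended with library weights, those of the germ cell and mitochondrial lists with no filter, that of the germ cell list at a filter of 5 FPKM and that of the mitochondrial list with quantile scaling.

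All 5 neutrophil genes were higher in HBOT than in CTX (mean 0.58, adjusted p = 0.00133, adjusted p = 0.654 with an estimated correlation), and 1 passed over the list alone, Csf3r, at 2.93 ± 0.398 against 1.5 ± 0.194 FPKM. The mean was 0.31 without CTX replicate 1 (adjusted p = 0.138), 0.38 without HBOT replicate 1 and 0.91 without CTX replicate 3 (adjusted p over all settings 2.33e-07 to 0.395). Smooth muscle and pericyte genes were higher in 9 of 13 (mean 0.23, adjusted p = 0.00560, adjusted p = 0.654 with an estimated correlation), with the calponin Cnn1 at 11 ± 2.84 against 7.07 ± 1.14 FPKM, and the pericyte markers Rgs5 (-0.26) and Cspg4 (-0.30) lower. The mean was 0.10 without HBOT replicate 1 (adjusted p = 0.285, over all settings 0.000555 to 0.285) and 0.34 without HBOT replicate 3. Of 13 inflammatory genes 7 were higher (mean 0.15, adjusted p = 0.0185, adjusted p = 0.520 with an estimated correlation), with Vcam1 at 11.3 ± 0.577 against 7.55 ± 0.548 FPKM and the chemokines Cxcl10 (-0.60) and Ccl5 (-0.46) lower. This call was lost without CTX replicate 1, where the mean was -0.03 (adjusted p = 0.386), without HBOT replicate 1 (0.10), HBOT replicate 2 (0.15) or HBOT replicate 3 (0.07), and the mean was 0.27 without CTX replicate 3 (adjusted p over all settings 0.00250 to 0.925). Over the list alone 0 members passed in the smooth muscle list and 0 in the inflammatory list. Interferon response genes were lower in 20 of 21 (mean -0.33, adjusted p = 0.0151, adjusted p = 0.883 with an estimated correlation), with Stat2 at 24.1 ± 3.04 against 31.9 ± 5.93 FPKM, Isg15 higher (0.42) and 0 passing over the list alone. This mean was -0.14 without CTX replicate 2 (adjusted p = 0.558), -0.10 without HBOT replicate 2 (adjusted p = 0.183), -0.37 without HBOT replicate 3 (adjusted p = 0.0834) and -0.52 without HBOT replicate 1 (over all settings 0.000641 to 0.558). The interferon and inflammatory calls also ended at a filter of 5 FPKM and with library weights, and the inflammatory call with median-of-ratios and quantile scaling.

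**Figure D3:**
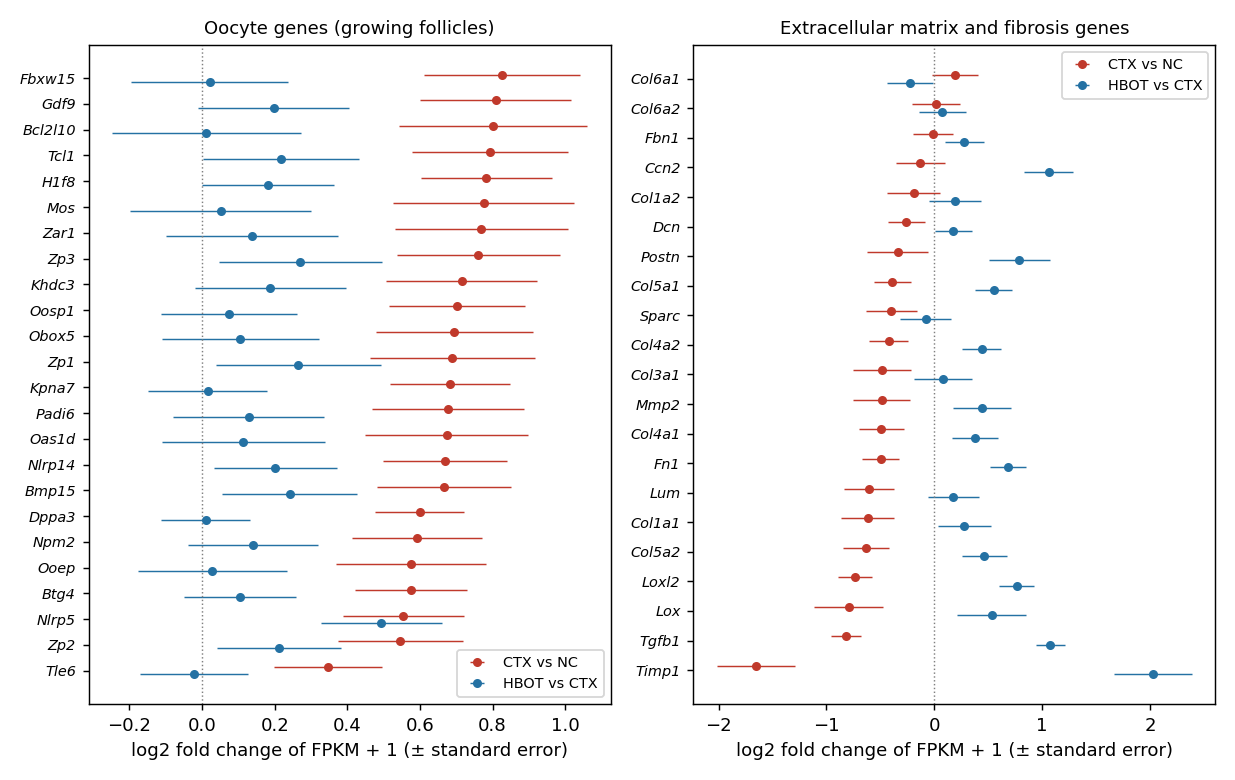
Log2 fold change of FPKM + 1 (point) with its standard error (line) for each measured member of the oocyte list (left) and the extracellular matrix list (right), for CTX against NC in red and HBOT against CTX in blue, with 3 libraries in each group. All 24 oocyte genes lie above 0 in CTX against NC, while 19 of 21 matrix genes lie below 0 in CTX against NC and 19 of 21 above 0 in HBOT against CTX.

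The lists that were not called in HBOT against CTX included granulosa cells (-0.04), theca and steroidogenesis (-0.01), corpus luteum (0.02), macrophages (0.08), T and NK cells (-0.05), and erythroid genes (-0.22). Among pathways, not called were DNA damage repair (-0.11), p53 targets (0.14), apoptosis (-0.09), antioxidant genes (0.0085), hypoxia targets (-0.04), nuclear-encoded oxidative phosphorylation (-0.12), DNA replication (-0.0041), cholesterol synthesis (-0.22) and adipose tissue (-0.55). Camera's direction was opposite to the mean for granulosa cells, DNA replication, hypoxia targets and T and NK cells, and the median was opposite to the mean for corpus luteum, antioxidant genes and the PI3K and FOXO list. DNA replication would have been called higher without CTX replicate 1 (0.16, adjusted p = 0.0267 by limma's camera) and cholesterol synthesis higher without CTX replicate 3 (0.17, adjusted p = 0.0270) but lower without CTX replicate 1 (-0.76, adjusted p = 3.42e-06). For 3 of the 33 lists the libraries did not overlap between the groups, where chance gives 10%, each with an exact permutation p of 0.1. Camera called 5 lists at a filter of 5 FPKM, 5 with library weights and 4 without both HBOT replicate 2 and CTX replicate 1, and fry called 0 in one direction.

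The comparison of HBOT with NC asks what still differed from the reference when hyperbaric oxygen was given with the drug. Oocyte genes were higher in HBOT than in NC (adjusted p = 0.317 with an estimated correlation), with Gdf9 at 76.8 ± 7.49 FPKM against 38.4 ± 8.74 and Zp3 at 64.1 ± 5.35 against 31.4 ± 7.23 (mean ± SD, n = 3). Genes of neutrophils, macrophages, red blood cells and inflammation were higher, including the adhesion molecule Vcam1 (ENSMUSG00000027962) at 11.3 ± 0.577 against 4.89 ± 1.02 FPKM. Corpus luteum genes were lower, with Akr1c18 at 1154 ± 1472 against 2367 ± 209. The log2 fold change of Akr1c18 was -1.94 and ran from -3.04 to -1.11 over all settings. With an estimated correlation 0 of these lists were called (smallest adjusted p = 0.258). With limma 0 of 13338 genes passed an adjusted p of 0.05, and the smallest was 0.235. Adjusted over the 15 panel genes alone, Gdf9 and Zp3 passed (adjusted p = 0.0104 each by limma).

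The genes with the smallest p that were higher in HBOT were Vcam1 (log2 fold change 1.08, SE 0.15), Ftdc1 (12.8 ± 0.889 against 6.76 ± 0.591 FPKM, 0.83), Nlrp5, Nlrp4a and the immune regulator Tnfaip8l2 (0.81), each at an adjusted p of 0.235 by limma. The oocyte genes Nlrp5 (27.1 ± 2.59 against 12.6 ± 1.82 FPKM, 1.05) and Nlrp4a (6.21 ± 0.619 against 3.13 ± 0.508 FPKM, 0.81) belong to the NLRP family expressed in oocytes. Those lower were the aminopeptidase Xpnpep2 (0.352 ± 0.183 against 5.83 ± 3.40 FPKM, -2.24) and the choline transporter-like Slc44a3 (-0.99), at the same adjusted p. So were the monoamine oxidase Maoa (11.3 ± 2.11 against 23.3 ± 3.6 FPKM, -0.98), the chromatin remodeller Smarca1 (39.8 ± 3.73 against 64.1 ± 1.48 FPKM, -0.68) and Tgoln1 (-0.54). Of the panel, Cyp17a1 was at 555 ± 236 against 70.2 ± 45.5 FPKM (3.07, SE 1.22, adjusted p = 0.126 over the panel alone by limma). Amh was at 237 ± 68.5 against 92.5 ± 30.6 (1.35), Cyp19a1 at 25.3 ± 26.4 against 5.26 ± 2.22 (1.59, SE 0.91) and the superoxide dismutase Sod2 at 17.1 ± 3.25 against 27.0 ± 6.77 (-0.62). The others had log2 fold changes of 0.40 for Ddx4, 0.29 for Fshr, -0.43 for Star, -0.09 for Mki67, 0.24 for Cdkn1a, 0.10 for Bax, -0.17 for Foxo3, -0.01 for Hmox1 and -0.33 for Vegfa. Star (0.85) and Fshr (-0.11) turned without HBOT replicate 1, Cdkn1a (-0.11), Foxo3 (0.11) and Hmox1 (0.19) without HBOT replicate 2, and Mki67 (0.12) without NC replicate 3. Over all settings Cyp19a1 ran from 0.78 to 2.56, Vegfa from -0.67 to -0.18, Ddx4 from 0.26 to 0.59 and Bax from 0.04 to 0.23.

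Unadjusted p-values under 0.05 were found for 1584 genes, 830 higher and 754 lower in HBOT, against 666.9 by chance, and 2740 genes (20.5%) did not overlap, where chance gives 10%. The balance of higher and lower turned with TPM (798 of 1796 higher), median-of-ratios (822 of 1754) and quantile scaling (871 of 1776), at a filter of 5 FPKM (554 of 1160) and without HBOT replicate 1 (742 of 1812) or 3 (909 of 2077), while without HBOT replicate 2 it was 1165 of 1740. At an absolute log2 fold change of at least 1, 101 of 229 were higher. The unadjusted count was 878 without NC replicate 1 and 902 without NC replicate 2. With library weights 181 genes passed under limma, 135 of them higher. Without HBOT replicate 3 there were 3 (B3gnt2, Commd1b and Qpct), without NC replicate 1 there was 1 (Rpl26), and without NC replicate 3 there was 1 (Mndal). With no filter 1 passed (MSTRG.25118.1), and without both HBOT replicate 2 and CTX replicate 1 there were 3 (H2-Q4, Tgtp1 and Kcnk3). In a fit of these 6 libraries alone 0 passed.

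Camera with a preset correlation called 12 lists in HBOT against NC, 11 higher and 1 lower, and 0 with an estimated correlation. A test with fry called 3 in one direction: the oocyte (adjusted p = 0.0487), neutrophil (0.0265) and inflammatory (0.0487) lists. All 24 oocyte genes were higher (mean 0.82, adjusted p = 2.26e-24 by limma's camera, adjusted p = 0.317 with an estimated correlation), with 23 passing over the list alone against 0 over all genes. The linker histone H1f8 was at 47.1 ± 3.01 against 23.8 ± 4.16 FPKM. The germ cell list had 10 of 13 members higher (mean 0.28, adjusted p = 0.00107, adjusted p = 0.541 with an estimated correlation), 3 passing over the list alone. These were the ubiquitin hydrolase Uchl1 (92.4 ± 4.19 against 48.9 ± 8.26 FPKM), the follicle transcription factor Nobox (10.2 ± 0.425 against 6.51 ± 0.735) and Elavl2 (2.63 ± 0.398 against 1.43 ± 0.265). Kit, Sohlh1 and Mael were not higher. The 11 corpus luteum genes were lower in 9 (mean -0.93, adjusted p = 0.0361, adjusted p = 0.541 with an estimated correlation). The 1 member that passed over the list alone, Ldhb, was higher, at 254 ± 17.1 against 153 ± 14.1 FPKM, and Sfrp4 was higher by 0.03. This call was lost without NC replicate 1 (-0.81, adjusted p = 0.126), NC replicate 2 (-0.85, adjusted p = 0.0790) or HBOT replicate 1 (-0.82, adjusted p = 0.329), at a filter of 5 FPKM and with median-of-ratios scaling (over all settings 0.00108 to 0.329).

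All 5 neutrophil genes were higher in HBOT than in NC (mean 1.79, adjusted p = 1.32e-06 by limma's camera, adjusted p = 0.258 with an estimated correlation), 4 passing over the list alone. As in CTX against NC, the filter favours a rise here for genes under 1 FPKM in all NC libraries. Csf3r was at 2.93 ± 0.398 against 0.613 ± 0.243 FPKM and S100a9 at 13.6 ± 7.27 against 0.637 ± 0.264. All 6 erythroid genes were higher (mean 1.59, adjusted p = 3.66e-05, adjusted p = 0.479 with an estimated correlation), 5 passing over the list alone, with Hba-a1 at 203 ± 100 against 55.0 ± 30.3 FPKM. For macrophages 15 of 16 were higher (mean 0.46, adjusted p = 2.07e-05, adjusted p = 0.530 with an estimated correlation), 2 passing over the list alone. These were C1qb (32.9 ± 9.05 against 19.3 ± 1.91 FPKM) and Ms4a7 (9.05 ± 4.38 against 3.31 ± 1.04), and Cx3cr1 was lower (-0.11). Of 13 inflammatory genes 11 were higher (mean 0.53, adjusted p = 0.00224, adjusted p = 0.258 with an estimated correlation), Vcam1 and the cytokine Il1b (1.99 ± 0.910 against 0.360 ± 0.370 FPKM) passing over the list alone and Il18 (-0.44) and Ccl2 (-0.10) lower. Without HBOT replicate 2 this list was not called (0.53, adjusted p = 0.0634, over all settings 0.000161 to 0.0634). All 8 T and NK cell genes were higher (mean 0.58, adjusted p = 0.00232, adjusted p = 0.479 with an estimated correlation), among them Gzmb at 1.56 ± 1.44 against 0.162 ± 0.0742 FPKM. Interferon genes were higher in 19 of 21 (mean 0.33, adjusted p = 0.00288, adjusted p = 0.828 with an estimated correlation), with Rtp4 at 14.3 ± 0.663 against 8.72 ± 2.85 FPKM, but not Bst2 (-0.12) and Xaf1 (-0.15). The interferon mean was 0.17 without NC replicate 2 (adjusted p = 0.160) and 0.16 without HBOT replicate 1 (adjusted p = 0.119), which end the call, and 0.55 without NC replicate 1 and 0.56 without HBOT replicate 2 (over all settings 5.83e-08 to 0.160). Over the list alone 0 members passed in the T and NK cell list and 0 in the interferon list.

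All 13 mitochondrially encoded genes were higher in HBOT (mean 0.26, adjusted p = 2.19e-05 by limma's camera, adjusted p = 0.530 with an estimated correlation), with mt-Co3 at 3610 ± 288 against 2762 ± 256 FPKM, and 0 passing over the list alone. DNA replication genes were higher in 21 of 22 (mean 0.29, adjusted p = 0.00107, adjusted p = 0.828 with an estimated correlation), such as Gins2 at 6.74 ± 0.201 against 4.40 ± 1.19 FPKM, with 0 passing over the list alone. Without HBOT replicate 2 this list was at 0.09 (adjusted p = 0.741, over all settings 6.47e-06 to 0.75), and with library weights it was not called. The unfolded protein and heat shock list was higher in 14 of 17 (mean 0.18, adjusted p = 0.0423, adjusted p = 0.765 with an estimated correlation). The transcription factor Xbp1 was at 130 ± 45.5 against 78.6 ± 9.57 FPKM, with the stress regulators Trib3 (-0.43) and Ddit3 (-0.31) lower, and 0 passing over the list alone. Of 23 other settings 13 ended its call, among them leaving out NC replicate 1 (0.12, adjusted p = 0.176), CTX replicate 1 (adjusted p = 0.0569), HBOT replicate 2 (0.12, adjusted p = 0.655) or HBOT replicate 3 (0.15, adjusted p = 0.109). Without HBOT replicate 1 it was at 0.28 (over all settings 0.000657 to 0.678).

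Among lists not called in HBOT against NC, the ovulation list was at 0.72 and the immediate early list at 0.16, and both rested on HBOT replicate 2. Without that library the immediate early list was at -0.53 and would have been called lower (adjusted p = 0.00183 by limma's camera). Granulosa cells (0.15), theca and steroidogenesis (-0.05), p53 targets (0.09), DNA damage repair (0.0076), antioxidant genes (-0.06), ferroptosis (-0.24) and endothelial cells (-0.15) were not called. The mean and median differed in sign for hypoxia targets (-0.02 and 0.0028), apoptosis (0.02 and -0.03) and cholesterol synthesis (-0.16 and 0.0014). For 8 of the 33 lists the libraries did not overlap between HBOT and NC, where chance gives 10%, each with an exact permutation p of 0.1.

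Whether HBOT moved genes back from their level in CTX was asked across all 13338 genes. The fold changes of CTX against NC and of HBOT against CTX use the same CTX libraries with opposite sign. An opposite direction is thus favoured with no effect at all. Its size was taken from 100 simulations of unchanged groups that kept the correlation between genes. They drew on the residuals of all 3 groups, so the spread of HBOT replicate 2 entered the simulated CTX libraries too. The simulations may therefore overstate the opposite direction that noise in the CTX libraries alone would give. As 0 genes passed in CTX against NC, the 1065 genes at an unadjusted p under 0.05 were used. Of these 72.3% had the opposite sign in HBOT against CTX, against a mean of 84.3% in the 92 simulations that gave a share, since 8 had no gene at that p. Both comparisons had an unadjusted p under 0.05 with opposite signs for 156 genes, 139 on average in the simulations (range 0 to 4730). A few large counts raise that average, and 87 of 100 simulations were at or below 156. Of the 156, 101 were lower in CTX and higher in HBOT (69.05 on average in the simulations, with 91 of 100 at or below 101). The other 55 were higher in CTX and lower in HBOT (69.68 on average, with 82 of 100 at or below 55). The covariance of the fold changes was -0.033 against a simulated mean of -0.040 (range -0.388 to 0.022), and their correlation across genes, which are not independent replicates, was -0.30 against -0.47. The covariance was 0.0072 above the simulated mean, less than the SD of 0.0081 over the fits that left out 1 library. The sign of this difference, taken against the value expected from noise, turned with library weights (-0.0022), without HBOT replicate 1 (-0.00030), without HBOT replicate 2 (-0.0012) and without both HBOT replicate 2 and CTX replicate 1 (-0.020). It shows neither reversal nor its absence.

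The fold changes of CTX and of HBOT, both against NC, had a covariance of 0.066 against a simulated mean of 0.041 (range -0.068 to 0.236) and a correlation across genes of 0.54 against 0.49. At an unadjusted p under 0.05 in both, 354 genes were higher (111 on average in the simulations, range 0 to 2175) and 136 lower (91.4, range 0 to 1853). Of the 100 simulations 92 were at or below 354 and 82 at or below 136. Both counts thus lay within the simulated range, and neither shows a shared change. With 3 libraries the NC group cannot be split into parts of at least 2, so part of these counts may come from the shared NC libraries.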

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

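The alternatives were set before the data were examined, apart from the GC and length correction, the fits without both HBOT library 2 and CTX library 1, and without HBOT library 2 at a pseudocount of 0.1, which were chosen after results were seen, as was taking the share of opposite signs over genes at an unadjusted p under 0.05 by limma. Of 4857 single-gene values under other settings, 68 passed where the main fit had not, some genes counting under several settings. The sign changed in 52 of 4857 values, in 19 of 205 results, none of which passed. For list means the sign changed in 156 of 2262 values, in 43 of 99 results, 3 of them called. By call, 68 became stronger, 138 weaker and 11 changed sign with a call on one side. The cause of these moves was not tested, but in CTX vs NC the spread of HBOT replicate 2 enters the fit of all 9 libraries.

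For genes changed in CTX vs NC, HBOT vs CTX and HBOT vs NC (0 in each), the counts were 123, 5 and 181 with library weights, 16, 2 and 3 without both libraries, 0, 1 and 1 with no filter, 31 in CTX vs NC with only the 2 groups compared and 7 there without HBOT library 2 at a pseudocount of 0.1. Leaving out each library gave 0 to 9, 0 to 1 and 0 to 3. Lists called were 0, 0 and 0 with an estimated inter-gene correlation and 0, 0 and 3 with fry, and in HBOT vs CTX 5 at FPKM of at least 5, 5 with library weights and 4 without both libraries.

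The list means that changed sign with a call on one side (lowest and highest when leaving out each library) were those of immediate early genes in HBOT vs NC (0.16; -0.53 to 0.64, -0.53 with library weights, -0.53 without both libraries, -0.56 without HBOT library 2 at a pseudocount of 0.1), cholesterol synthesis in CTX vs NC (0.05; -0.33 to 0.60) and in HBOT vs CTX (-0.22; -0.76 to 0.17), and, in HBOT vs CTX, the oocyte list (0.14; -0.026 to 0.23), the germ cell list (0.08; -0.051 to 0.18), DNA replication (-0.0041; -0.20 to 0.16) and inflammatory genes (0.15; -0.033 to 0.27, -0.050 without both libraries).

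The covariance for reversal, less its value from noise, was 0.0077, -0.0022 with library weights, -0.020 without both libraries and -0.0012 to 0.019 when leaving out each library. With only the 2 groups compared it was not run, since it needs all 3. Replicate number as a block changed 0 gene calls and no list count (12, 10 and 12). Same-numbered libraries had correlations of -0.287 to 0.156 in 9 pairs, 2 of them above 0.1, and in 5 of the 9 pairs the same-numbered correlation was above the highest with another number.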

Other observations

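The class I and class II histocompatibility genes, chosen only after their values had been seen and tested as no fixed list, were higher in CTX than in NC. Of 15 class I genes 14 were higher (mean log2 fold change 1.01), of 7 class II genes 6 (1.29) and of 11 interferon-inducible GTPases 11 (1.53), with H2-Aa at 65.8 ± 24.6 against 16.4 ± 6.87 FPKM and Tap2 (-0.16) and H2-Eb1 (-0.27) lower. Under limma 0 of these 33 passed in the fit of all libraries, 4 in the fit of the 2 groups compared, 22 with library weights, 3 without HBOT replicate 2 and 8 without both HBOT library 2 and CTX library 1. The means of the 3 groups of genes in HBOT were -0.35, -0.25 and -0.67 against CTX and 0.65, 1.04 and 0.87 against NC. The macrophage (0.38), T and NK cell (0.64) and neutrophil (1.21) lists were higher in CTX too, and immune cells express class II genes, so a larger share of these cells stays open, as does the division of reads among near-identical copies of H2-Q, Tgtp1 and Tgtp2.

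The tests of HBOT replicate 2 were written before they were run, but after the library was seen to stand apart. After the GC and length correction 1582 genes still lay more than 1 log2 unit from the other libraries, against 340 at most elsewhere, which argues against that bias as the whole cause. Of the 8 ovulation genes below the filter, 8 were highest in this library, among them Ereg (361 against at most 0.964 FPKM) and Sult1e1 (223 against at most 0.0327). An ovary taken after an ovulatory gonadotropin surge would give this. The test is weak, as the filter leaves out genes that reach 1 FPKM in fewer than 3 libraries. The measured members of the list also already lay 2.40 log2 units above the NC mean in this library. Of 10 clock-controlled genes 5 lay outside the other libraries in the direction set, which does not settle a different time of day. Arntl, Npas2 and Clock, set as higher, did not, and Npas2 was below all other libraries (0.421 against at least 0.578 FPKM). Per2 also differed between groups, at most 4.13 FPKM in NC and at least 6.23 in CTX, with HBOT between. In NC replicates 1 and 2 Arntl was at 8.62 and 9.86 FPKM (at most 5.37 in CTX) and Npas2 at 3.21 and 2.97 (at most 1.48). Per3 was lower there, at 7.45 and 6.31 (at least 10.7 in CTX), as were Tef, at 32.7 and 28.0 (at least 39.5), and Hlf, at 1.64 and 1.38 (at least 1.85). For these genes NC replicate 3 lay within the CTX range. Clock was at least 7.55 in NC and at most 7.45 in CTX, and Bhlhe41 at most 1.81 in NC and at least 1.87 in CTX. Nr1d2 and Ciart overlapped between NC and CTX. A different time of day between groups was not tested and stays open for the contrasts with NC. Cycle stage was not measured, so the surge stays open.

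The tests of the oocyte list, higher in CTX and in HBOT than in NC, were chosen only after results were seen. The mean in CTX against NC was 0.65 after the GC and length correction and at least 0.62 under the 3 scalings, which argues against bias and scaling as its source. A smaller share of the rest of the ovary would raise all oocyte genes alike, but at a pseudocount of 0.1 the list was higher than the germ cell list by 0.49 (SE 0.17), which speaks against that cause alone. The germ cell list holds Kit and Uchl1, which other cells express too, so this is a weak test. Whether follicle stages, oocyte state or cycle stage differed stays open.

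The tests of the matrix list, lower in CTX and higher in HBOT than in CTX, were also chosen only after results were seen. With the fall taken from 1 CTX library and the rise from the other 2, the smallest change over the 3 divisions was 0.302 against an SD of 0.171 between libraries of a group, so noise in the shared CTX libraries is not ruled out. In CTX against NC the mean was -0.475 after the GC and length correction, and the vessel and smooth muscle lists were at -0.072 (SE 0.099), which argues against that bias and against a loss of those cells as the source of the lower level in CTX. In HBOT against CTX the smooth muscle and pericyte list was higher as well (0.23, adjusted p = 0.00560 by limma's camera, adjusted p = 0.654 with an estimated correlation), so a part of those cells in that comparison stays open. A smaller share of fibroblasts in CTX stays open too.

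A test of the 6 CTX and HBOT libraries against the 3 NC libraries was also chosen after results were seen. It called 0 of 33 lists after adjustment (smallest adjusted exact p 0.0982), so a change shared by both groups is neither shown nor excluded. With so few libraries no list could pass this adjustment alone, whatever the size of its change. The smallest possible exact permutation p, 0.0119, was reached by 4 lists, erythroid (1.70), neutrophil (1.5), oocyte (0.75) and T and NK cell (0.61).

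Splits of each pair of groups, planned in advance, number 10 and cannot give a share under 0.05. Genes at an unadjusted p under 0.05 by limma numbered 1065 in CTX vs NC (highest other split 650, 1 split as high), 812 in HBOT vs CTX (1335, 3 splits) and 1584 in HBOT vs NC (1265, 1 split). Lists called numbered 12 in CTX vs NC (17, 6 splits as high), 10 in HBOT vs CTX (17, 7 splits) and 12 in HBOT vs NC (13, 4 splits), the real split included in each. Whether other splits call as many lists as the real one because genes of a list vary together, or because of structure between the samples, was not tested, and with an estimated correlation 0 lists were called in each comparison.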
